A study of Danio rerio with 4 samples.

How the data were processed

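RNA was measured in zebrafish (Danio rerio, strain AB) at 72 hours post fertilization (hpf) that had been kept from 4 hpf in dimethyl sulfoxide (DMSO, the solvent control) or in 4 µM bisphenol C (BPC, a bisphenol). Each group had 2 libraries, numbered 1 and 3 in the labels. The labels do not say how many larvae went into a library or whether libraries came from separate clutches. The p-values of single genes therefore measure the spread between these libraries, which may be technical in part. Per the labels' protocols, polyadenylated RNA was selected, fragmented and made into paired-end Illumina libraries in which the second cDNA strand was marked with dUTP. Whether strand was used in counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty.

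The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene and library for 27472 genes, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR, with no role for each. The genome build and annotation are not given in the sources used here, and no coordinates are printed. In the authors' deposited table of BPC against DMSO, the ratio is that of the mean FPKM values, the log2 change is its log2, and each gene has a p-value and a q-value. A further deposited table holds the authors' KEGG pathway enrichment for a single pair of libraries, BPC 3 against DMSO 3, with gene numbers and a p-value per pathway, and a gene list with ratio and log2 values of that pair. The depth of each library is unknown, because the values carry no read totals and low values show no common step from which whole reads could be recovered. Intervals from read counts were therefore not computed. All FPKM columns (0 left unmatched) were matched to samples by name.

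The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an intensity trend in the prior spread and no robust fit. Genes with at least 0.5 FPKM in at least 2 libraries were tested (19873 genes), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, two-sided. A log2 change on this scale understates the change of low genes. The fitted prior had 4.47 degrees of freedom. Some genes listed at 0 can be failed estimates: 17 genes were at 0 in 1 BPC library and at 5 FPKM or more in the other, against 1 such gene in DMSO. Where a gene is listed at 0 the library values are given and no fold. Near-identical copies (globins, crystallins, opsins, hatching enzymes, cathepsin L, trypsins and her4 genes) share reads, so the split between copies is uncertain.

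Before the data were examined, 42 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Of 1319 list symbols, 1209 were matched through the files' own symbols and then a table of Ensembl IDs and symbols, which held 25272 of the IDs. Lists were tested with camera (limma, preset inter-gene correlation 0.01) where at least 5 members were tested, with Benjamini-Hochberg adjustment over 41 lists. KEGG pathways in the deposited annotation with 10 to 500 tested members were tested likewise. At the preset correlation, camera p-values compare members with other genes and do not measure the spread between libraries. List medians are given relative to the median of all tested genes. The genes named were the 12 largest changes in each direction among genes past the threshold with non-overlapping groups, a mean of at least 1 FPKM and a symbol that is no clone name; up to 4 members of a list with the smallest p, or, where none passed, the 2 with the highest level; and a fixed set made of fabp10a, fabp2, prss1, ins, pcna, mcm5, cyp1a, cyp19a1b and vtg1, with 1 further gene that is not reported here, nor is 1 list. Genes outside this rule are said to be chosen after their values were seen.

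Corrections were made after values had been seen. A symbol shared by several Ensembl IDs is now matched to the ID whose symbol in the name table is the same; this gave the hatching gland list 1 more tested member, 8 in all, and lowered its adjusted p. The pattern that recognises clone names was narrowed, and the share of mitochondrial transcripts, first computed without the protein-coding genes, was recomputed with them. A test of scaling on ribosomal protein genes by median centring had a fixed outcome and was replaced by a comparison with genes of like level. The oxidative phosphorylation test takes the transcripts to be short from general knowledge; its verdict was for a time set to open because the set includes large proteins, and was put back after the small subunits alone had been measured. The ribosomal share is that of KEGG ribosome genes not described as mitochondrial.

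The scripts were tested on simulated data for 19873 genes made from the real means, with 200 genes changed in each of 10 draws. Only genes above a set mean level were changed, and 2-fold and 4-fold refer to the log2(FPKM + 1) scale. In the real test 24.6% of genes were called, a far larger share than was changed here. Recovery and the share of unchanged genes among calls depend on that share, so the values below check the scripts and do not describe the real calls. With spreads drawn from the fitted prior, 63.7% of the genes changed 2-fold and 98.0% of those changed 4-fold were recovered on average, and unchanged genes made up 6.31% of the calls (4.79 to 8.82% over draws). With the moderated spreads of the real fit, 96.5% and 99.6% were recovered, and unchanged genes made up 10.9% of the calls (5.39 to 13.9%), above the nominal share of 0.05. In those draws the refitted prior had 10.2 degrees of freedom on average against 4.47 in the real fit. A limit on recovery was first set for both fold sizes, was not met for 2-fold changes, and was then kept for 4-fold changes alone. A limit on unchanged genes was dropped in the same rewrite and then put back. The limit of 7.5% on unchanged genes among calls was set after first draws had been seen and applies to the spreads drawn from the prior. Of 40 simulated unchanged lists, 0 were called by camera, and the list shifted by 0.5 was called. The simulated genes were independent, so this could not reveal false list calls from correlated members. Estimated correlations of the real lists reached 0.808.

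Alternatives fixed beforehand were other pseudocounts (0.1 and 0.01), no filter, a filter of 5 FPKM, the replicate number as a block, leaving out each library, stricter thresholds (0.01, or 2-fold), quantile normalization and genes with a symbol only, meaning that clone, locus and accession names were left out. For lists they were an estimated correlation, fry, the block, no filter and leaving out each library. Median centring, scaling to equal FPKM totals (TPM scaling) and quantile normalization for lists were added after the data were seen. The deposited list of links to pathway maps was not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.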

Results

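Whole-larva expression was compared between 2 libraries of DMSO larvae and 2 libraries of larvae exposed to 4 µM BPC, all at 72 hpf. The series title concerns proliferation of liver and intestinal cells under BPC, and the comparison asks which transcripts differ with exposure. FPKM totals were 355583 and 355364 in DMSO and 422245 and 425611 in BPC. Ribosomal protein genes took 9.34 and 9.13% of the total in DMSO and 15.7 and 13.1% in BPC, globins 1.26 and 1.23% against 2.87 and 2.88%, and mitochondrially encoded transcripts 11.5 and 12.4% against 7.33 and 6.74%. Across genes, which are not independent replicates, the log2 values correlated at 0.989 in the DMSO pair, 0.972 in the BPC pair and 0.928 to 0.941 between groups.

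In BPC larvae, cone photoreceptor and digestive enzyme transcripts were far lower, and embryonic globin, hatching enzyme and lens crystallin transcripts were higher. The ultraviolet cone opsin opn1sw1 fell from 365 ± 41.6 to 2.92 ± 3.54 FPKM (SD, n = 2, log2 change -6.92, SE 0.62, adjusted p = 0.00212). The embryonic globin hbbe3 rose from 2.77 ± 3.05 to 334 ± 173 FPKM (log2 change 6.66, adjusted p = 0.0023), and the hatching enzyme he1.1 rose from 3.29 ± 0.265 to 152 ± 66.3 FPKM (log2 change 5.09, adjusted p = 0.000562). The liver fatty acid binding protein fabp10a fell from 55.3 and 36.2 FPKM in the DMSO libraries to 1.64 and 2.96 in the BPC libraries (log2 change -3.82, adjusted p = 0.00102).

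Of 19873 genes tested with limma, 1404 were higher and 3480 lower in BPC (24.6% of those tested), and 255 and 758 of these changed at least 2-fold. The split depends on scaling: lower calls were 71.3% of all calls in the main test, 52.0% after quantile normalization and 90.6% after TPM scaling, while median centring gave 2441 higher and 1997 lower genes. Quantile normalization, median centring and TPM scaling moved the median of all tested genes, -0.12 in the main test, by 0.14, 0.15 and -0.25 in turn. Leaving out DMSO replicate 1 left 329 higher and 675 lower genes, and leaving out DMSO replicate 3 left 411 and 892. The 24 genes with the largest changes kept their calls under every alternative run for them.

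Among those genes, the other higher ones were hbae5 (3.36 and 0.832 FPKM in DMSO, 64.2 and 63.1 in BPC), he1.2, crybb1, cryba1b, per1b, cox4i1l and 4 Ensembl genes that share the symbol ctslb (ENSDARG00000074306, ENSDARG00000095072, ENSDARG00000087651 and ENSDARG00000039173), with log2 changes from 2.92 to 4.52. The other lower ones were the opsins opn1lw2 and opn1sw2, the cone transducin subunits gngt2b, gnb3b and gnat2, the cone arrestin arr3a and the recoverin gene rcvrn3, with log2 changes from -6.37 to -4.22. The green cone opsin opn1mw1 was listed at 171 and 118 FPKM in DMSO and at 0 and 1.26 in BPC. The photoreceptor disc gene prph2a was listed at 24.2 and 20.5 against 0 and 0.41, scpp5 at 19.4 and 21.4 against 0 and 0.0994, and the trypsin gene prss59.2 at 21.8 and 28.5 against 0 and 0.

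**Figure D1:**
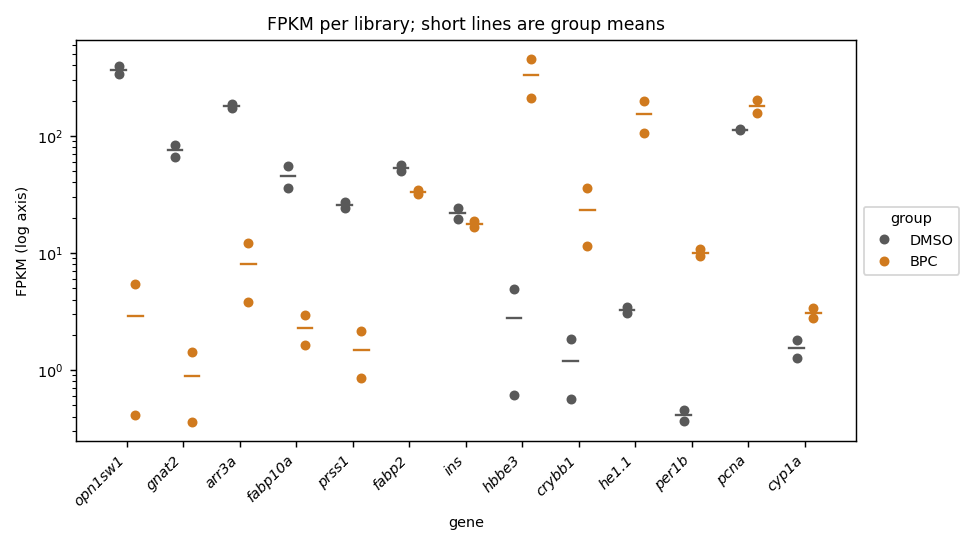
FPKM (log axis) of named genes in each library, with DMSO in grey and BPC in orange; points are libraries and short lines are group means (n = 2). Both BPC libraries lie below both DMSO libraries for opn1sw1, at 0.413 and 5.42 against 394 and 335 FPKM, and above them for hbbe3.

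Eye and nervous system lists moved apart. Of 51 tested photoreceptor and retinal pigment epithelium genes, 42 fell and 0 rose (1 higher and 42 lower adjusted over the list alone), and the list median lay 2.27 below that of all genes (relative log2 median -2.27, camera adjusted p = 2.66e-18). The cone phosphodiesterase subunit pde6ha fell from 34.4 ± 3.16 to 1.12 ± 0.345 FPKM and arr3b from 20.2 ± 0.37 to 0.486 ± 0.283. Of 31 lens crystallin and fibre genes, 19 rose and 0 fell (23 and 0 adjusted over the list alone, relative median 1.29, adjusted p = 1.85e-13); lim2.1 rose from 8.69 ± 0.206 to 29.3 ± 4.25 FPKM. Of 36 neural and retinal progenitor genes, 18 rose, among them the Notch ligand dlb, and 2 fell, rx1 among them (20 and 3 adjusted over the list alone, relative median 0.69, adjusted p = 4.22e-08). These 3 lists had adjusted p = 0.447 with an estimated correlation. With fry the photoreceptor list was called (adjusted p = 0.0366), but the lens (0.0974) and progenitor (0.11) lists were not. Of 39 neuron genes, 27 fell and 0 rose (30 and 1 adjusted over the list alone, relative median -0.61, adjusted p = 3.15e-08, and adjusted p = 0.549 with an estimated correlation). The sodium pump subunit atp1a3b fell from 21.5 ± 2.35 to 7.06 ± 1.45 FPKM and the glycine transporter slc6a5 from 9.71 ± 1.26 to 3.85 ± 0.383. Of 13 myelinating glia genes, 4 fell, mbpa and mpz among them, and 3 rose (5 and 3 adjusted over the list alone); the list did not pass (adjusted p = 0.506).

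Digestive organ and endocrine lists were lower. Of 15 exocrine pancreas genes, 13 fell and 0 rose (14 and 1 adjusted over the list alone, relative median -1.82, adjusted p = 3.15e-08); prss1, a trypsin, fell from 24.4 and 27.2 FPKM to 0.851 and 2.14, and cpa5 from 17.6 ± 0.859 to 0.946 ± 0.452. Of 27 enterocyte genes, 19 fell and 1 rose (20 and 2 adjusted over the list alone, relative median -0.61, adjusted p = 8.13e-06); the brush border gene vil1 fell from 7.33 ± 0.92 to 0.397 ± 0.277 FPKM, and fabp2 from 53.4 ± 4.28 to 33.4 ± 1.75. The fabp2 call was lost without DMSO replicate 1 (adjusted p = 0.0595, and 0.0676 for foxa3) and without DMSO replicate 3 (adjusted p = 0.0982). Of 22 liver and gut transcription factors, 12 fell, including cdx1b, nr1h4 and foxa3, and 1 rose (12 and 2 adjusted over the list alone, relative median -0.31, adjusted p = 0.0404). Of 17 endocrine pancreas and enteroendocrine genes, 6 fell and 0 rose, the same adjusted over the list alone (relative median -0.20, adjusted p = 0.0257). The 4 with the smallest p were vipb, neurod1, pyyb and scg3. Of these, neurod1 fell from 89.5 ± 1.21 to 47.9 ± 7.26 FPKM, and pyyb was listed at 2.48 and 2.06 against 0 and 0.554. Whole-larva values do not show in which tissue these genes fell. The insulin gene ins was 21.8 ± 3.47 FPKM in DMSO and 17.8 ± 1.43 in BPC (log2 change -0.27, adjusted p = 0.191, or -0.53 and 0.0293 with TPM scaling). These 4 lists had adjusted p = 0.447 with an estimated correlation. The transcription factor list was not called without DMSO replicate 1 (adjusted p = 0.137) or BPC replicate 1 (0.128), nor the endocrine list without the same libraries (0.116 and 0.0546); with TPM scaling the values were 0.0549 and 0.0519.

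Hepatocyte genes went both ways. Of 33 tested, 12 fell and 6 rose, the same adjusted over the list alone, and the list did not pass (relative median -0.12, adjusted p = 0.354; 0.00658 after quantile normalization). Besides fabp10a, the urate oxidase gene uox fell from 21.4 ± 4.67 to 2.93 ± 0.323 FPKM, and hpda and gc fell. Of 32 complement and coagulation genes, 6 rose and 5 fell, the same adjusted over the list alone (relative median 0.24, adjusted p = 0.0364, and adjusted p = 0.447 with an estimated correlation); c3a.2 and c3a.3 fell and prozb rose. That call was lost without DMSO replicate 1 (adjusted p = 0.0725), DMSO replicate 3 (0.153) or BPC replicate 3 (0.247), and with median centring (0.0737) or quantile normalization (0.217). Of 16 bile acid genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone, relative median -0.66, adjusted p = 0.00467, and adjusted p = 0.447 with an estimated correlation). The sterol hydroxylase gene cyp8b1 fell from 7.08 ± 1.24 to 0.343 ± 0.0842 FPKM, and slc27a2a rose from 26.2 ± 8.01 to 93.9 ± 14.8. The bile acid call was lost without DMSO replicate 1 (adjusted p = 0.899) and without DMSO replicate 3 (0.588). Of 25 cholesterol synthesis genes, 11 fell and 0 rose (16 and 1 adjusted over the list alone, relative median -0.50, adjusted p = 0.0133, and adjusted p = 0.615 with an estimated correlation; 0.0821 without DMSO replicate 1); hmgcs1 fell from 14.0 ± 0.124 to 5.31 ± 0.0155 FPKM. Of 39 fatty acid metabolism genes, 15 fell and 3 rose (18 and 3 adjusted over the list alone, relative median -0.25, adjusted p = 0.0136, and adjusted p = 0.447 with an estimated correlation), with hadhaa and cpt2 among the lower.

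DNA replication and mitosis lists were higher by camera, but not called with fry, in whole larvae, a measurement that does not separate liver or intestine from other tissues. Of 45 mitosis genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone, relative median 0.44, adjusted p = 4.95e-11, adjusted p = 0.447 with an estimated correlation, and fry adjusted p = 0.101). The kinase gene aurkb rose from 9.46 ± 0.227 to 16.0 ± 1.26 FPKM. Of 47 DNA replication genes, 6 rose and 0 fell, the same adjusted over the list alone (relative median 0.35, adjusted p = 7.66e-08, adjusted p = 0.549 with an estimated correlation, and fry adjusted p = 0.244). The replication clamp gene pcna rose from 113 ± 2.07 to 180 ± 32.3 FPKM (log2 change 0.66, SE 0.15, adjusted p = 0.0233), mcm7 rose from 18.2 ± 0.155 to 28.5 ± 0.169, and mcm5 was 23.3 ± 1.99 and 28.7 ± 3.84 (adjusted p = 0.157). Without DMSO replicate 1 or DMSO replicate 3 these calls were lost while the log2 changes stayed close: 0.67 or 0.64 for pcna (adjusted p = 0.13 or 0.137), 0.62 or 0.63 for mcm7 (0.0889 or 0.0726) and 0.72 or 0.68 for aurkb (0.0655 or 0.0679). The mcm5 call was gained without BPC replicate 3 (0.0413). The pcna call was also lost with quantile normalization (0.104), TPM scaling (0.071) and no filter (0.062). Of 59 ribosome biogenesis genes, 4 rose and 2 fell (2 and 2 adjusted over the list alone, relative median 0.17, adjusted p = 0.0295, and adjusted p = 0.752 with an estimated correlation). That call was lost without DMSO replicate 3 (0.211), without BPC replicate 1 (0.776), with TPM scaling (0.305) and after quantile normalization (0.13). Of 33 proteasome genes, 1 rose and 2 fell (0 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.388).

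Receptor and xenobiotic lists did not pass with camera. With fry, which does not set members against other genes, 3 were lower: the aryl hydrocarbon receptor list (fry adjusted p = 0.025), other xenobiotic metabolism and thyroid axis (0.0171 each). Of 10 tested genes in the aryl hydrocarbon receptor list, 2 rose and 1 fell (2 and 2 adjusted over the list alone, adjusted p = 0.843). The list also holds receptor genes: the fall was that of ahr1b, a receptor, and the rises those of the targets cyp1a and cyp1b1. The list's median and mean lay below 0 while camera's direction was upward. The cyp1b1 call was lost with no filter (adjusted p = 0.0591), without DMSO replicate 1 and without BPC replicate 1. Its log2 change, 0.89 in the main test, was 0.70 without DMSO replicate 1 and 0.77 without BPC replicate 1. The monooxygenase gene cyp1a rose from 1.53 ± 0.374 to 3.09 ± 0.45 FPKM (log2 change 0.69, adjusted p = 0.028), a call lost without DMSO replicate 1 (0.0652), DMSO replicate 3 (0.173) or BPC replicate 1 (0.0754) and with no filter (0.0746). Of 40 other xenobiotic metabolism genes, 16 fell, gsta.1 among them, and 5 rose, sult1st4 among them (19 and 7 adjusted over the list alone, adjusted p = 0.145). Of the oestrogen response list 3 genes were tested, too few for camera; esrrga, an orphan receptor gene, fell, 1 of 3 in either adjustment, but not without DMSO replicate 1 (0.0966) or DMSO replicate 3 (0.12), with no filter (0.0752) or with median centring (0.0608). The brain aromatase gene cyp19a1b (0.104 ± 0.000252 and 0.281 ± 0.189 FPKM) and the yolk protein gene vtg1 (0.189 ± 0.0779 and 0.0825 ± 0.0434) were below the filter. Of 16 thyroid axis genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 0.318); thyroglobulin (tg) fell from 2.81 ± 0.501 to 0.562 ± 0.108 FPKM, and ttr was listed at 1.25 and 1.08 against 0 and 0. Of 16 glucocorticoid axis genes, 5 fell and 1, cyp17a1, rose (6 and 1 adjusted over the list alone, adjusted p = 0.506).

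Blood, skin, pigment, heart and hatching gland lists were higher. Of 24 erythroid genes, 15 rose and 1 fell, the same adjusted over the list alone (relative median 0.99, adjusted p = 7.14e-11). Of 32 epidermis genes, 19 rose and 3 fell (21 and 3 adjusted over the list alone, relative median 0.76, adjusted p = 8.87e-09); anxa1c rose from 29.0 ± 0.285 to 178 ± 5.58 FPKM, and anxa1b fell. Of 22 pigment cell genes, 14 rose and 2 fell (14 and 3 adjusted over the list alone, relative median 0.99, adjusted p = 3.01e-08); the melanosome transporter gene slc45a2 rose from 4.22 ± 0.436 to 16.9 ± 1.26 FPKM. Of 16 cardiac muscle genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, relative median 0.43, adjusted p = 0.00177); the natriuretic peptide gene nppa rose from 3.72 ± 0.132 to 21.9 ± 5.71 FPKM. Of 8 hatching gland genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone, relative median 0.62, adjusted p = 0.00714; 0.0576 with no filter), with agr2 among the lower. These 5 lists had adjusted p = 0.447 with an estimated correlation. With fry the cardiac muscle (adjusted p = 0.0611) and pigment (0.0503) lists were not called. Of 43 skeletal muscle genes, 6 fell and 3 rose, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.551), but its direction was not stable: it was higher without BPC replicate 3 (0.00426) and lower after quantile normalization (0.000759). Of 27 endothelial genes, 2 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.122; 0.0322 after quantile normalization).

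Skeletal and ionocyte lists were lower. Of 35 cartilage and bone genes, 14 fell and 1 rose (19 and 3 adjusted over the list alone, relative median -0.38, adjusted p = 0.00918, and adjusted p = 0.658 with an estimated correlation); the cartilage proteoglycan gene acanb fell from 6.51 ± 0.442 to 2.47 ± 0.294 FPKM. Of 22 ionocyte genes, 12 fell and 1 rose, the same adjusted over the list alone (relative median -0.45, adjusted p = 0.00533, and adjusted p = 0.447 with an estimated correlation); the calcium channel gene trpv6 fell from 4.75 ± 0.0486 to 1.29 ± 0.073 FPKM. Of 16 neutrophil genes, 4 fell (cpa5, mpx, lcp1 and abcb9) and 0 rose, the same adjusted over the list alone. The list did not pass with camera (adjusted p = 0.128) but was lower with fry (0.0366). The largest fall, that of cpa5 (log2 change -3.27), is also counted in the exocrine pancreas list. The abcb9 and lcp1 calls were lost with quantile normalization (adjusted p = 0.183 and 0.0728), median centring (0.113 and 0.0744) and no filter (0.0946 and 0.0685). Both were also lost without DMSO replicate 1 or DMSO replicate 3, abcb9 without BPC replicate 1 and lcp1 without BPC replicate 3. The abcb9 call was lost too with pseudocounts of 0.1 (0.0575) and 0.01 (0.0638) and with the replicate block (0.0545). The mpx call was lost without DMSO replicate 1 (0.126), with no filter (0.0597) and with quantile normalization (0.0526). Of 15 macrophage genes, 1 fell, ccl34b.1, in either adjustment (adjusted p = 0.851), and its call was lost without DMSO replicate 1 (0.0532).

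**Figure D2:**
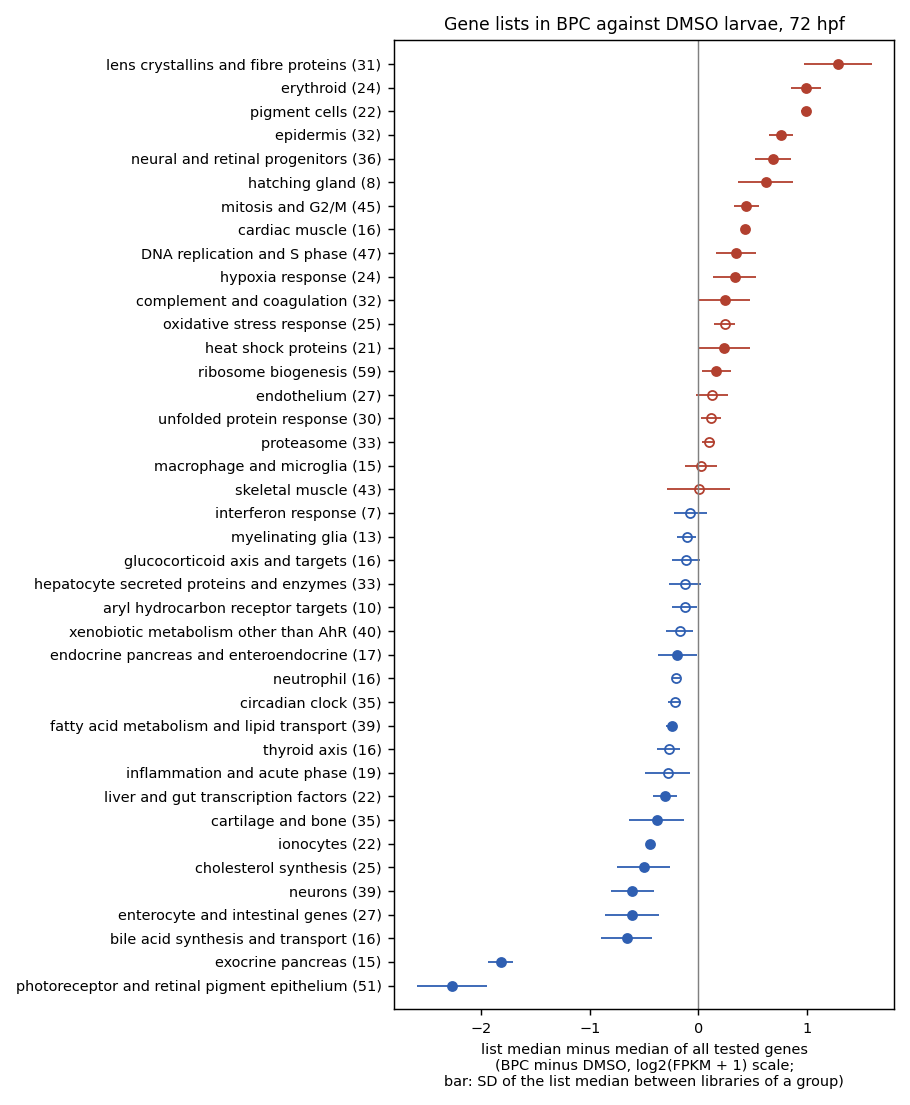
Median log2 change of gene lists (BPC minus DMSO, log2(FPKM + 1) scale) relative to the median of all tested genes, with tested members in brackets; bars are the SD of the list median between libraries of a group, and filled points had a camera adjusted p under 0.05. The photoreceptor list lies lowest at -2.27 and the lens list highest at 1.29.

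Hypoxia, oxidative stress and unfolded protein response genes changed in both directions. Of 24 hypoxia response genes, 6 rose, egln3 among them, and 4 fell (8 and 5 adjusted over the list alone, relative median 0.33, adjusted p = 0.0285, and adjusted p = 0.549 with an estimated correlation; 0.0754 after median centring and 0.199 after quantile normalization). Of 21 heat shock genes, 3 rose, hspb9 among them, and 1 fell (1 and 0 adjusted over the list alone, relative median 0.24, adjusted p = 0.0462, and adjusted p = 0.698 with an estimated correlation). The heat shock call was lost without DMSO replicate 1 (0.114), DMSO replicate 3 (0.0533) or BPC replicate 1 (0.461), and with median centring (0.0737) or quantile normalization (0.462). Of 30 unfolded protein response genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone, adjusted p = 0.3). Of 25 oxidative stress genes, 4 rose, nfe2l2a and sqstm1 among them, and 5 fell, the catalase gene cat among them (6 and 6 adjusted over the list alone, adjusted p = 0.153). Of 19 inflammation genes, 4 fell, leap2 among them, and 0 rose (5 and 1 adjusted over the list alone, adjusted p = 0.259, and lower with fry at 0.0446). Of 7 interferon response genes, 0 changed (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.861); stat1a was 9.06 ± 0.338 and 6.92 ± 0.0354 FPKM, and irf9 was 3.05 ± 0.131 and 2.08 ± 0.56. With TPM scaling stat1a (-0.61, adjusted p = 0.0109) and irf9 (-0.71, adjusted p = 0.0311) were called lower, and irf9 also without BPC replicate 3 (-0.59, adjusted p = 0.0272).

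Circadian clock genes changed in both directions. Of 35 tested, 14 rose and 13 fell (15 and 17 adjusted over the list alone). The period gene per1b rose from 0.411 ± 0.0592 to 10.1 ± 0.968 FPKM (log2 change 2.97, SE 0.14, adjusted p = 0.000357), tefa rose from 6.94 ± 0.187 to 44.8 ± 3.32, and ciarta rose from 4.76 ± 0.0563 to 23.7 ± 0.273. The cryptochrome gene cry3b fell from 20.6 ± 1.39 to 6.35 ± 0.427 FPKM. The list as a whole did not pass (adjusted p = 0.145; 0.00851 with TPM scaling); its median was -0.34, its mean 0.12 and camera's direction upward.

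Of 147 KEGG pathways in the deposited annotation, 13 were higher and 16 lower by camera, and 0 were called with an estimated correlation (smallest adjusted p = 0.859). In the ribosome pathway 80 of 128 genes rose and 14 fell (relative median 0.82, adjusted p = 1.93e-17). Spliceosome (21 of 133 higher, 4 lower; adjusted p = 1.13e-07) and DNA replication (6 of 36 higher, 1 lower; adjusted p = 6.94e-06) were also higher. The cell cycle pathway was called higher (adjusted p = 0.00395) with 12 of 130 genes higher and 11 lower (relative median 0.16). Cardiac muscle contraction (37 of 98 lower, 6 higher; adjusted p = 0.0126) and adrenergic signaling in cardiomyocytes (67 of 186 lower, 10 higher; adjusted p = 0.00758) were lower, opposite to the cardiac muscle list. In phototransduction 23 of 34 genes fell and 0 rose (relative median -0.78, adjusted p = 2.28e-08). Tryptophan metabolism (26 of 46 lower, 4 higher; adjusted p = 0.000685), oxidative phosphorylation (43 of 134 lower, 5 higher; adjusted p = 0.0033) and fatty acid degradation (23 of 43 lower, 3 higher; adjusted p = 0.00758) were lower.

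The authors' deposited table marks 2302 genes, 533 higher and 1769 lower, each with at least a 2-fold ratio and a q-value under 0.05. Among the 19873 genes tested here it marks 468 higher and 1568 lower, of which 423 and 1517 were called in the same direction, 96 were not called and 0 were called in the opposite direction. Independent lists of these sizes would share 33.1 and 275 genes, but both come from the same libraries. The authors' deposited table of KEGG enrichment, from BPC 3 against DMSO 3 alone and so without a replicate check, lists 135 pathways, 21 with an unadjusted p under 0.05. Purine metabolism held 31 of its 424 genes (4 higher, 27 lower) and phototransduction 14, all lower, in the authors' deposited table.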

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

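Median centring, TPM scaling and quantile normalization of lists were chosen after the data were seen; the other alternatives were planned. The count of 1404 higher genes became 748 with no filter, 2441 with median centring, 759 with TPM scaling, 255 with a 2-fold threshold and 391 at an adjusted p under 0.01. The count of 3480 lower genes became 2020, 1997, 7286, 758 and 977 under the same settings, 1602 with a filter of 5 FPKM and 2111 with quantile normalization. A stricter threshold lowers these counts by construction, and a stricter filter leaves genes out. Median centring and TPM scaling shift the genes of a library together. They moved the median of all tested genes by 0.15 and -0.25, and the split moved the same way by construction. With no filter, 734 of the 1404 higher and 1887 of the 3480 lower genes kept their calls. The cause of those losses, and of the change with quantile normalization, was not tested. Leaving out a library gave 329 to 2097 higher and 675 to 4146 lower genes, with a lone library assumed to vary like the other group; the lowest counts came without DMSO replicate 1, which leaves the BPC pair to set the spread. With the replicate block 1333 genes were higher and 3282 lower, and 1229 of the 1404 higher and 3068 of the 3480 lower main calls were kept. Same-numbered libraries deviated together at a correlation of 0.00805 over genes, so the numbers were not taken to pair the libraries. Under the block 4 of 168 called genes named by the rule, which favours small p and large changes, lost their call and 0 lists did. Of the 14 lists higher, 0 remained past the threshold with an estimated correlation and 3 lists were higher with fry; of the 11 lower, 0 remained with an estimated correlation, and 12 lists were lower with fry. With fry 15 of the 25 called lists lost their call, and 5 lists not called by camera were lower. Among the lost were neurons, lens, mitosis, DNA replication, progenitors, cardiac muscle, pigment, cartilage and cholesterol synthesis. Leaving out a library gave 11 to 14 higher and 6 to 11 lower lists, and 11 to 16 higher and 10 to 15 lower pathways against 13 and 16. With an estimated correlation 0 pathways were higher and 0 lower. An estimated correlation also makes camera take its degrees of freedom from the 4 libraries instead of the genes. Fatty acid metabolism and ionocytes lost their camera calls with estimates of -0.0236 and -0.00999, below the preset 0.01. A higher correlation was not the cause for these lists. The cause of list and pathway changes under the other alternatives was not tested. Outside fry and the estimated correlation, 15 of the 25 called lists kept their call under every alternative run, and 105 of the 168 called genes did. No named gene or list past the threshold changed direction in these alternatives. Relative log expression factors, DESeq2 and voom were not run, because the values are FPKM and not counts. The depth is unknown, so what it limits cannot be stated.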

Other observations

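The tests of FPKM scaling, eye tissue, clock phase and lighting, and the sets of smooth muscle genes, small subunits and mitochondrial ribosome genes, were chosen after related results were seen; the early-embryonic, neuropeptide and oxidative phosphorylation tests were written before their values were seen. Smooth muscle genes, outside the fixed lists, were lower in BPC: 7 of 11 tested fell and 0 rose, among them acta2 (log2 change -3.06, limma adjusted p = 0.00104), myh11a (-2.11) and desmb (-1.83), with camera p = 0.000916 and p = 0.145 with an estimated correlation. Genes of the ribosome pathway without those described as mitochondrial, a set that still held MRPS12 and the biogenesis gene rsl24d1, were higher in 80 of 86 cases and lower in 0; rps23, chosen after its value was seen, rose from 394 to 1286 FPKM on average (log2 change 1.70).

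With camera at the preset correlation, photoreceptor, neuron and digestive lists were lower while lens, erythroid, progenitor, mitosis and pigment lists were higher. With an estimated correlation 0 lists passed, and with fry the neuron, lens, progenitor, mitosis and pigment lists did not. A scaling factor per library moves all genes alike and argues poorly for these opposite shifts. The photoreceptor and lens medians lay -3.56 apart, with a spread of 0.448 between libraries. Loss of whole eyes is argued against by the lens median, 1.29 above that of all genes. The lens median does not address loss of retina alone, because retinal pigment epithelium genes were not tested apart from the photoreceptor list. An earlier developmental stage of the BPC larvae may account for the pattern: early-embryonic genes, none in the fixed lists, had a median 0.37 above all genes (10 of 25 higher, 0 lower; camera p = 3.53e-06, p = 0.2 with an estimated correlation), while neuropeptide and hormone genes, 7 of 36 in the fixed lists, lay at -0.27 with camera p = 0.0641 and did not decide. Stage, a direct effect of BPC and a difference between clutches stay open, as the labels give no staging.

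Of 11 clock genes known to peak near dawn 8 rose and 1, dbpa, fell (log2 change -0.64), and of 9 that peak near dusk 7 fell and 0 rose, all in the fixed clock list. The set medians lay 1.82 apart, and with an estimated correlation camera p was 0.0286 for the dawn set and 0.0855 for the dusk set. This is consistent with the groups being at different clock phases when sampled. Light-induced genes, 3 of 5 from the fixed list, had a median 0.55 above all genes (2 of 5 higher, 0 lower, camera p = 9.41e-05, p = 0.0576 with an estimated correlation), so different lighting at sampling may also contribute. The labels give a cycle of light and dark, but the time of day at sampling is not given in the sources used here. If it differed between the groups, it could not be told apart from exposure. An effect of BPC on the clock therefore stays open and untested.

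Ribosomal protein transcripts were higher, and library scaling is argued against by their median, 0.74 above that of 259 other genes of like level in DMSO (67 higher, 33 lower), with a spread of 0.129 between libraries. Loss of long messenger RNAs, which would raise other short ones too, is argued against as the whole cause by nuclear oxidative phosphorylation genes, with a median of -0.14 relative to all genes (5 of 121 higher, 37 lower). The subunits known to be small proteins lay at -0.09 (4 of 54 higher, 15 lower) and mitochondrial genes of the ribosome pathway at -0.07 (0 of 42 higher, 14 lower). These sets all serve mitochondria, and a fall of their own could hide a rise of short transcripts, so they do not exclude such a loss. Transcript lengths themselves were not analysed here. A difference in stage or growth was not tested separately and stays open.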
